A study of Mus musculus with 6 samples.

How the data were processed

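Dorsal root ganglia of lumbar levels 3, 4 and 5 from 6 pooled samples, 3 vehicle and 3 vincristine, were measured by RNA sequencing; each pool held tissue of 4 female C57BL/6 mice. Groups and replicate numbers were taken from the sample titles; the names of the deposited tables number vehicle replicate 3 as 4 and give 10 µg in place of the labels' cumulative 40 µg. Per the labels' protocols, RNA was kept in RNAlater, extracted on columns and made into stranded total RNA libraries, which were read on a NextSeq instrument as single-end reads of 75 nucleotides.

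The deposited values are raw counts of reads per gene symbol, with no normalization, in 1 table per sample. STAR, SAMtools and HTSeq were used with the mouse build mm10 (GRCm38), per the submitters' processing notes. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands may have been shared. HTSeq as a rule keeps only uniquely aligned reads that fall in 1 gene, which lowers the counts of near-identical gene copies such as the globins. Each table lists 38926 gene symbols and ends with the counter's summary lines, which were kept out of library sizes and tests. Of all tallied alignments, in which a read with several alignments can enter more than once, 31.1% to 40.5% were not unique, 14.8% to 24.8% fell outside annotated genes and 0.253% to 0.331% were ambiguous. Reads in genes ranged from 12374331 to 26346304 per library, and depth limits genes of low count most in vincristine replicate 1.

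Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults (minimum count 10) left 16706 genes, TMM factors scaled the libraries, and estimateDisp (robust), glmQLFit (robust, with the default dispersion method of this version) and glmQLFTest gave two-sided p-values, adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. The model held the treatment group only and left 4 residual degrees of freedom; the common biological coefficient of variation was 0.193. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. Another scaling moved the median gene by at most 0.0159 on the log2 scale. Replicates were compared before averaging: the chi-square statistic per degree of freedom between libraries of a group was far above 1 for each pair, so no library was a copy of another. The first principal component held 56.4% of the variance and set vincristine replicate 1 apart; its sample quality weight in limma was 0.194.

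Gene lists, 46 in number, were fixed before the data were examined and cover the cell types of the ganglion, neighbouring tissues, ion channels, the cytoskeleton, stress and immune pathways. Some genes, such as Atf3, Cdkn1a, Lcn2 and C1qc, belong to several lists, so counts of different lists can hold the same gene. Of 1074 list entries 9 were matched under an older symbol and 6 had no match. Each list with at least 5 tested members was tested with camera of limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were alternatives. A list's value per library is the median over members of log2 CPM minus the mean of the vehicle libraries. The 4 supplementary lists, of B-cell precursor, mature B-cell, immature red cell and globin genes, were written after the called genes had been seen; they serve only the weighing of the B-lineage and red cell patterns in the additional observations.

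Genes were named by a rule fixed before the data were examined. It took the 10 largest increases and 10 largest decreases among called genes with a mean of at least 1 CPM over all 6 libraries whose groups did not overlap, passing over genes without an official name. It also took up to 4 members with the smallest p in the direction of each called list, up to 2 of any other list, and 16 genes of injury, pain and microtubule biology whatever their values. The decreases ran out of called genes before 10 were reached. Gene positions come from GENCODE M21 on GRCm38, matched by symbol for 37390 of the 38926 symbols. A ratio with 1 to 3 reads in a group has an exact conditional 95% interval, which covers counting error only.

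Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters on low counts, other dispersion settings, the replicate number as a block, counts thinned to the smallest library, leaving out mitochondrially encoded genes, a threshold of 0.1 and leaving out each library in turn. Sample quality weights, the newer dispersion method of edgeR and DESeq2 with a library left out were added after the data were seen. The edgeR and DESeq2 steps were tested on simulated counts for the comparison of vincristine with vehicle over 16706 genes, with 50 genes changed at each fold size. Of these, edgeR recovered 2 at 1.5-fold, 25 at 2-fold, 42 at 4-fold and 48 at 8-fold with 8 false calls, and DESeq2 7, 34, 43 and 49 with 43 false calls. The counts were drawn once from edgeR's own dispersions with no library set apart, unlike the real data. In simulated lists for the same comparison, 0 of 46 unchanged lists were called, and a list raised 2-fold had an adjusted p of 3.68e-40 with the preset and 0.00567 with an estimated correlation; these simulated genes vary independently, unlike real ones.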

Results

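Dorsal root ganglia hold the cell bodies of the sensory neurons that innervate limbs and trunk, together with satellite glia, Schwann cells, vessels and immune cells. Ganglia of lumbar levels 3, 4 and 5 on the treated side were taken from female C57BL/6 mice aged 8 to 10 weeks, and tissue of 4 animals was pooled into each sample. Total RNA was sequenced from 3 vehicle samples and 3 vincristine samples, each pool being a separate biological replicate. Per the labels, the vincristine animals had received a cumulative 40 µg of the drug into the paw; the names of the deposited tables give 10 µg, and how these doses relate is not given in the sources used here. Vincristine is a vinca alkaloid used in cancer chemotherapy that binds tubulin, and peripheral neuropathy is a known side effect. The vehicle libraries held 17967934, 19546519 and 19917055 reads counted in genes, and the vincristine libraries 12374331, 19406150 and 26346304. The comparison between these groups addresses which transcripts of the ganglia differ after the drug. In all, 16706 genes had enough reads to be tested.

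Genes known to be induced in injured sensory neurons were far higher in the vincristine libraries. Atf3, a transcription factor switched on in axotomised neurons, was at 7.19 ± 1.01 CPM in vehicle and 205 ± 80.2 CPM in vincristine (SD, n = 3 each), a log2 fold change of 4.83 ± 0.33 (SE; edgeR adjusted p = 0.00732). Sprr1a, a small proline-rich protein of regenerating axons, went from 0.302 ± 0.187 to 54.8 ± 24.7 CPM (log2 7.50 ± 0.53, edgeR adjusted p = 0.00732). Nts, which encodes the peptide neurotensin, went from 9.60 ± 1.66 to 192 ± 54.9 CPM (log2 4.32 ± 0.27, edgeR adjusted p = 0.00732). The axon injury and regeneration list, fixed before the data were examined, had 27 tested members, and 27 of them had a positive log2 fold change. Of these members 13 rose past the threshold over all genes by edgeR, 23 did when adjusted over the list alone, and 14 did not pass over all genes; DESeq2 called 19. The list's median log2 fold change was 1.59, with medians of 1.32, 1.51 and 1.85 in vincristine replicates 1, 2 and 3 against the vehicle mean. The list passed camera with a preset correlation (adjusted p = 9.09e-94), and not with an estimated correlation (adjusted p = 0.153). The estimated correlation was 0.50 against the preset 0.01, so the p-value with the preset overstates the evidence.

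**Figure D1:**
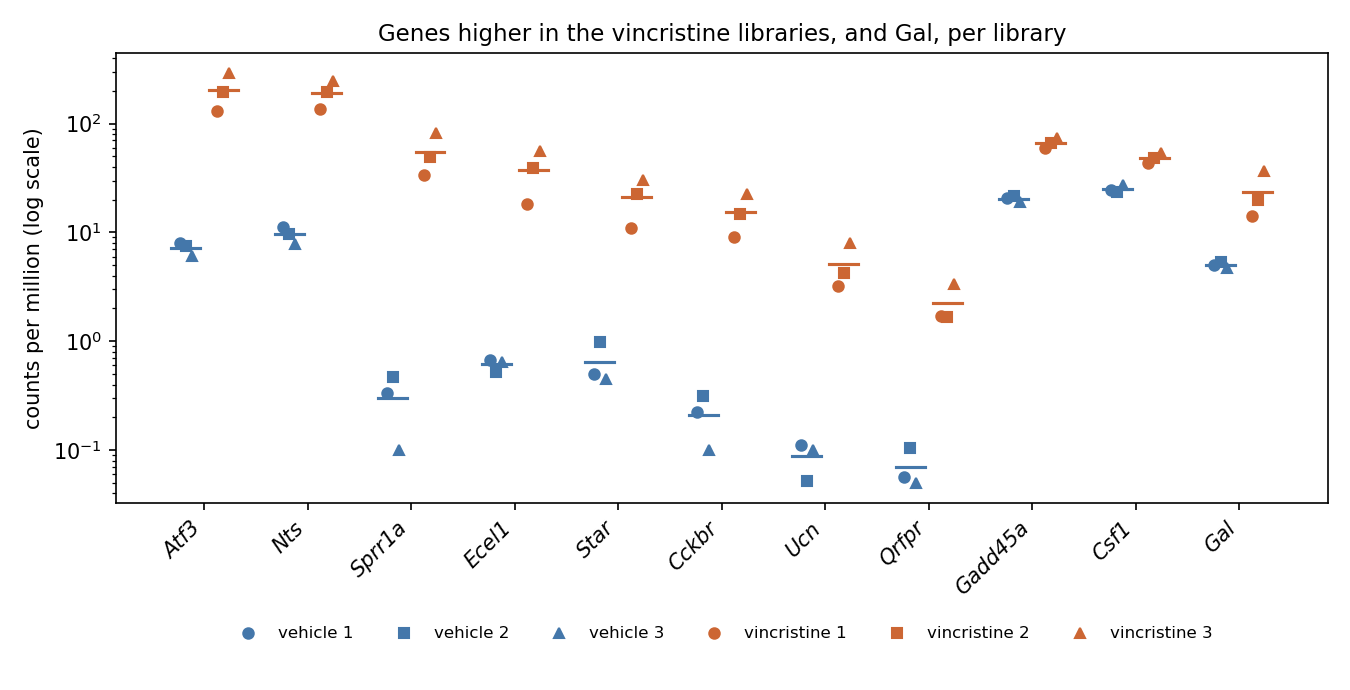
CPM (log axis) of 11 genes in each of the 6 libraries; blue marks are vehicle, orange marks are vincristine, the marker shape gives the replicate, and each short bar is a group mean. The vincristine values lie above the vehicle values for each gene shown, with Atf3 means of 7.19 and 205 CPM.

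In all, 60 genes differed between the groups at an adjusted p under 0.05, 49 of them higher and 11 lower after vincristine. The largest increases among named genes with a mean of at least 1 CPM over all 6 libraries, after Sprr1a, were in Lipn (a lipase), Cckbr (the cholecystokinin B receptor, log2 6.16 ± 0.50), Ecel1 (a membrane peptidase related to endothelin-converting enzyme, 5.93 ± 0.49) and Ucn (urocortin, 5.80 ± 0.55). Lipn had 1 read over the 3 vehicle libraries and 195 over the 3 vincristine libraries, a ratio of 192 with an exact 95% counting interval of 34.0 to 7612. Star, which carries cholesterol into mitochondria for steroid synthesis, followed with a log2 fold change of 5.04 ± 0.49. The receptor gene Qrfpr rose by 4.91 ± 0.54 and the growth factor gene Fgf3 by 4.82 ± 0.66 on the log2 scale. Gadd45a, a stress-induced growth arrest gene, rose from 20.4 ± 1.33 to 66.2 ± 7.32 CPM, and the macrophage growth factor gene Csf1 from 25.2 ± 1.87 to 48.2 ± 4.84 CPM (edgeR adjusted p = 0.00732 and 0.0308). A gene on the opposite strand overlaps Gadd45a, and the strand setting of the counting is not given in the sources used here. The same limit applies to Ppp1r15a, Ddit3, Cdkn1a, Cx3cr1, Ube2c, Il1b, Kcnj3, Scn9a, Lss, Cyp51, Mb, Myh2 and Slc32a1. Other called members of the injury list, named here after their values were seen, were Npy (neuropeptide Y, log2 4.26), Gpr151 (4.07), Tnfrsf12a (2.14), Flrt3 (1.95) and Socs3 (0.99). Stmn4, a stathmin that binds tubulin, rose by 2.43 ± 0.27 on the log2 scale. Galanin (Gal) was at 5.02 ± 0.285 CPM in vehicle and 23.5 ± 11.7 CPM in vincristine (log2 2.23 ± 0.35); it was called by DESeq2 and not by edgeR (edgeR adjusted p = 0.0692). Its edgeR adjusted p was 0.00581 and 0.0422 without vincristine replicates 1 and 3, and between 0.141 and 0.357 without any other library. The number of called genes moved with each library. It was 346 without vincristine replicate 1, 6 without vincristine replicate 2 and 18 without vincristine replicate 3. It was 0 by edgeR without vehicle replicate 1, 2 or 3, where 1462, 1063 and 1409 genes were at an unadjusted p under 0.05 and DESeq2 called 316, 206 and 319. With all 6 libraries DESeq2 called 551 genes, 60 of them shared with edgeR. On the simulated counts DESeq2 made 43 false calls and edgeR 8. Those counts were drawn once, from edgeR's own dispersions, with independent genes and no library set apart. They therefore cannot rank the methods on the real libraries. Genes that passed by DESeq2 alone are taken as less certain, here and below, because edgeR did not call them.

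The lead genes lie on several chromosomes of GRCm38 (GENCODE M21). Atf3 spans chromosome 1 from 191170296 to 191218039, Sprr1a chromosome 3 from 92483952 to 92485895, and Nts chromosome 10 from 102481756 to 102490486. Among the genes that fell, Ms4a1 spans chromosome 19 from 11249675 to 11266241 and Rag1 chromosome 2 from 101638282 to 101649501. Each is protein-coding.

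Several genes of the B-cell lineage fell. Ms4a1, which encodes the B-cell surface protein CD20, went from 12.5 ± 4.99 to 0.512 ± 0.257 CPM (log2 -4.65 ± 0.44, edgeR adjusted p = 0.0158). Vpreb3, a pre-B-cell receptor gene, had a log2 fold change of -4.44 ± 0.49, and Rag1, a recombinase of lymphocyte precursors, of -4.17 ± 0.51. Another gene overlaps Rag1 on the same strand, so its count is less certain. Faim3 (-3.64 ± 0.37), Cd79a (-3.55 ± 0.37), the B-cell coactivator Pou2af1 (-3.13 ± 0.36), Cd79b (-2.75 ± 0.34) and the kinase gene Blk (-2.35 ± 0.32) also fell. The list of B and plasma cell markers had 12 tested members, of which 6 fell over all genes tested by edgeR, 7 fell by DESeq2, 7 fell when adjusted over the list alone, and 6 did not pass over all genes. Its median log2 fold change was -2.55, and its medians against the vehicle mean were -1.89, -2.66 and -2.59 in vincristine replicates 1, 2 and 3. It passed camera with the preset correlation (adjusted p = 3.66e-23) and not with an estimated correlation (adjusted p = 0.203). Immunoglobulin genes, named after their values were seen, did not pass: log2 fold changes were -0.46 for Ighm, 0.08 for Igkc and 1.54 for Igj. Of the 12 tested list members 3 had a positive log2 fold change, so the fall did not take in the whole list.

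**Figure D2:**
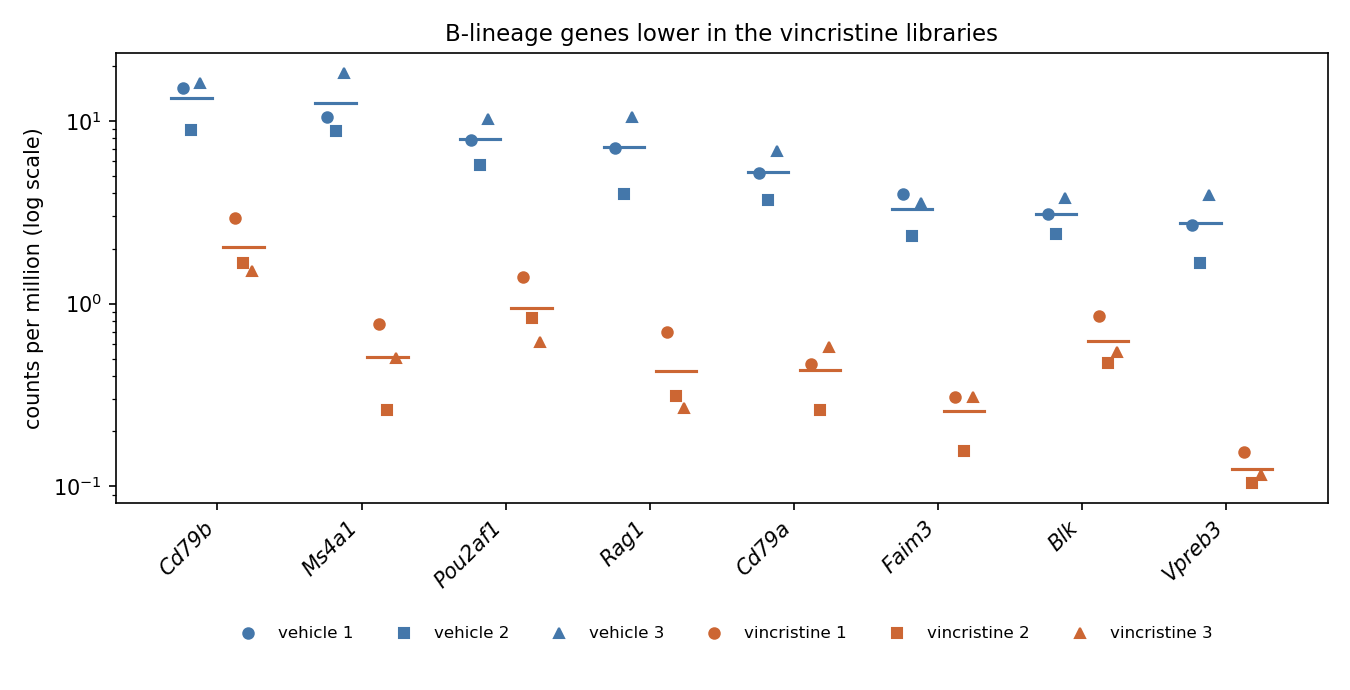
CPM (log axis) of 8 genes that fell, in each of the 6 libraries; blue marks are vehicle, orange marks are vincristine, the marker shape gives the replicate, and each short bar is a group mean. For each gene the vincristine values lie below the vehicle values; the Ms4a1 means are 12.5 and 0.512 CPM.

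By edgeR, few members of the stress-response lists rose past the threshold over all genes. In the unfolded protein and integrated stress response list, 2 of 25 tested members rose over all genes and 8 when adjusted over the list alone. Trib3, a pseudokinase gene induced by ATF4, went from 2.25 ± 0.366 to 8.83 ± 1.15 CPM. Chac1, a glutathione-degrading enzyme gene, went from 2.86 ± 0.314 to 10.7 ± 2.53 CPM (edgeR adjusted p = 0.0164 and 0.0273 for the pair). Ppp1r15a (log2 1.22 ± 0.18, edgeR adjusted p = 0.0530) and Ddit3 (0.78 ± 0.13, edgeR adjusted p = 0.0850) passed by DESeq2 and not by edgeR. In this list DESeq2 called 6 members, and 12 were higher at an unadjusted p under 0.05. The list's median was 0.33 (camera adjusted p = 1.20e-09, and adjusted p = 0.179 with an estimated correlation). In the immediate early gene list 1 of 22 members rose over all genes, Atf3, and 8 did when adjusted over the list alone; DESeq2 called 5, and 8 were higher at an unadjusted p under 0.05. Its median was 0.30 (adjusted p = 3.69e-09, and adjusted p = 0.203 with an estimated correlation), with Nr4a3 at 1.33 ± 0.26, Fosl2 at 0.86 ± 0.17 and Fos at 0.77 ± 0.14, each past the threshold by DESeq2 and not by edgeR. Among p53 targets 1 of 24 members rose over all genes and 3 when adjusted over the list alone; DESeq2 called 3, and 6 were higher at an unadjusted p under 0.05. The gene called by edgeR over all genes was Gdf15, a stress cytokine gene at 0.105 ± 0.00612 CPM in vehicle and 0.703 ± 0.0630 CPM in vincristine (edgeR adjusted p = 0.0497). Both means lie below 1 CPM, so the call rests on few reads and the small SDs are no measure of precision. The p53 list's median was 0.22 (adjusted p = 0.00206, and adjusted p = 0.633 with an estimated correlation), and 0.14 without vehicle replicate 3; Cdkn1a, at 0.83 ± 0.16, passed by DESeq2 and not by edgeR (edgeR adjusted p = 0.126). Glucocorticoid-responsive genes had a median of 0.27 (adjusted p = 0.000772, and adjusted p = 0.633 with an estimated correlation), with 0 of 18 members called over all genes by edgeR and 6 when adjusted over the list alone. Of these members 6 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 5, each higher. Those called by DESeq2 include Lcn2, also in the neutrophil list, and Cdkn1a, also in the p53 list, so they are not a separate response. Without vehicle replicate 3 the median was 0.15.

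**Figure D3:**
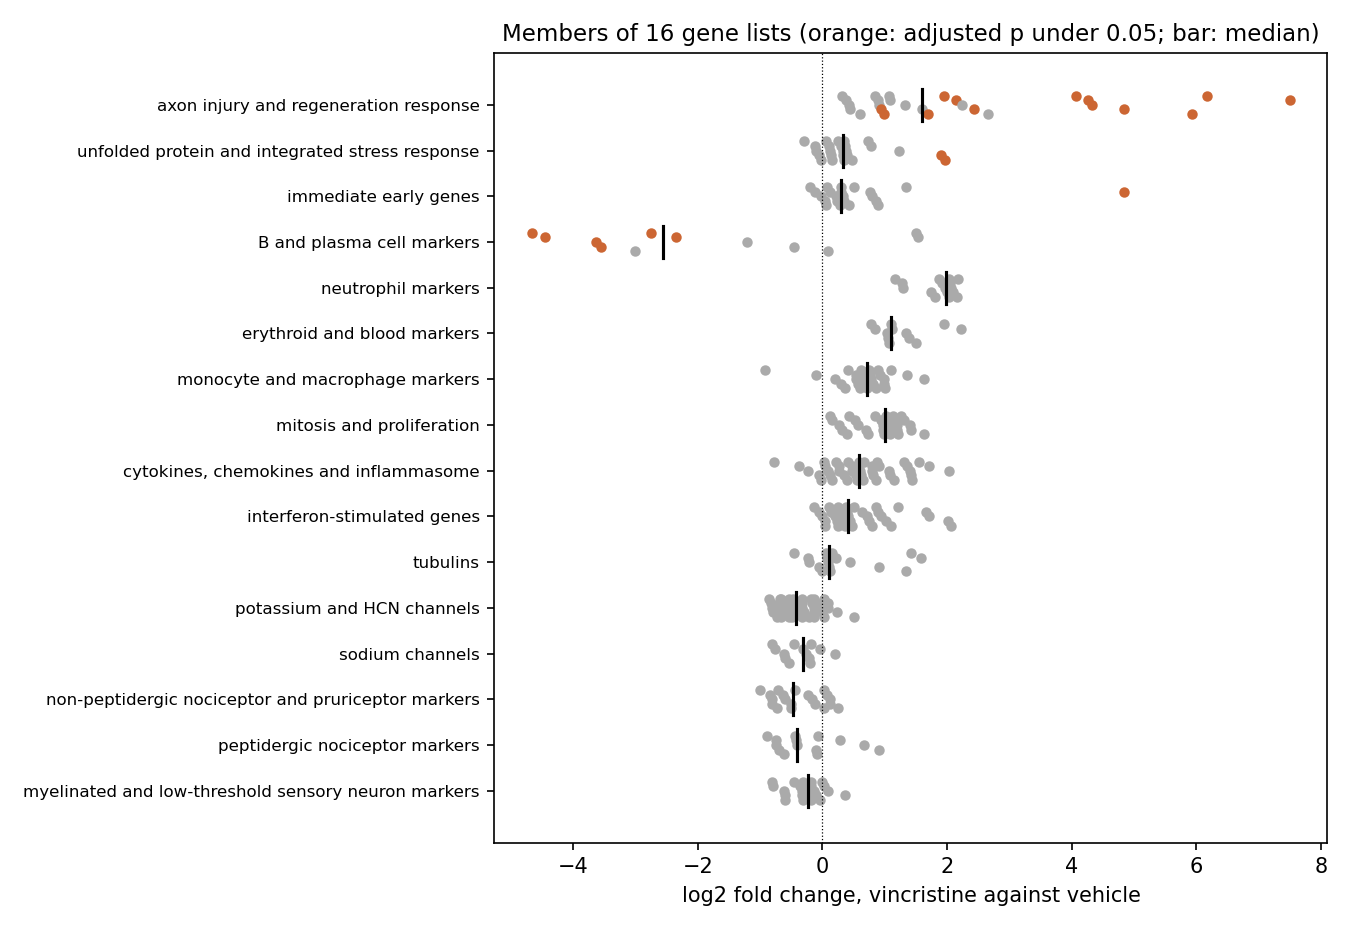
Log2 fold change (horizontal axis, vincristine against vehicle) of each tested member of 16 gene lists; orange points passed an adjusted p of 0.05, grey points did not, and the black bar is the list median. The injury list has 13 orange points on the right and the B-cell list 6 on the left, and most other lists have none.

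Markers of myeloid and red blood cells were higher, most of all in vincristine replicate 1. Neutrophil markers had a median log2 fold change of 1.98 over 16 members, with medians of 2.81, 1.28 and 1.42 in vincristine replicates 1, 2 and 3. Over all genes 0 of them passed by edgeR (15 at an unadjusted p under 0.05, 13 by DESeq2), and 14 passed when adjusted over the list alone. Ltf (lactoferrin) went from 136 ± 34.4 to 614 ± 363 CPM, and Csf3r, Mmp8 and Lcn2 had log2 fold changes of 1.81, 2.10 and 2.17. The list passed with the preset correlation (adjusted p = 3.66e-23) and not with an estimated correlation (adjusted p = 0.436), and its median was 1.29 without vincristine replicate 1. Erythroid and blood markers had a median of 1.10 over 12 members, 0 called over all genes and 10 when adjusted over the list alone (11 at an unadjusted p under 0.05, 7 by DESeq2). Its medians were 1.82, 0.53 and 0.83 in the vincristine replicates (adjusted p = 1.45e-13, and adjusted p = 0.551 with an estimated correlation). Slc4a1, the red cell anion exchanger gene, was at 156 ± 34.6 and 604 ± 259 CPM (edgeR adjusted p = 0.0871). The erythroid median was 0.65 without vincristine replicate 1. Monocyte and macrophage markers had a median of 0.71 over 28 members, 0 called over all genes and, adjusted over the list alone, 19 higher and 1 lower. At an unadjusted p under 0.05, 21 were higher and 1 lower, and DESeq2 called 7 higher and 1 lower (list adjusted p = 1.45e-13, and adjusted p = 0.633 with an estimated correlation). Itgam (1.63), C1qc (0.71), the fractalkine receptor gene Cx3cr1 (0.72) and Emr1 (0.61) passed by DESeq2 and not by edgeR; another gene overlaps Itgam on the same strand. The list median was 0.47 without vincristine replicate 1. Cell-division genes had a median of 1.01 over 30 members, 0 of them called by edgeR over all genes and 0 when adjusted over the list alone (18 at an unadjusted p under 0.05, 6 by DESeq2; list adjusted p = 2.04e-12, and adjusted p = 0.633 with an estimated correlation). Their medians were 1.74, 0.50 and 0.52 in the vincristine replicates, and the list median fell to 0.49 without replicate 1; Ube2c and Cenpe had log2 fold changes of 1.63 and 1.26.

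Inflammatory mediators were higher as lists, and edgeR called none of their members. Cytokines, chemokines and inflammasome genes had a median of 0.59 over 43 members, 0 called by edgeR over all genes and 11 when adjusted over the list alone. In this list 21 were at an unadjusted p under 0.05, and DESeq2 called 7 (list adjusted p = 4.53e-11, and adjusted p = 0.633 with an estimated correlation); the median was 0.31 without vincristine replicate 1. The cytokine medians were 1.02, 0.34 and 0.39 in vincristine replicates 1, 2 and 3, beside 2.81, 1.28 and 1.42 for neutrophil markers and 1.11, 0.37 and 0.54 for monocyte and macrophage markers. Il1b was at 2.21 ± 0.560 CPM in vehicle and 5.56 ± 3.70 CPM in vincristine, and Nlrp3, the inflammasome sensor gene, at 3.25 ± 0.892 and 6.85 ± 2.23 CPM (edgeR adjusted p = 0.365 and 0.263; not called by DESeq2). The interleukin-1 receptor antagonist gene Il1rn (2.02), Cxcl14 (1.36), Ccl2 (1.09) and Il1r1 (0.67) passed by DESeq2 and not by edgeR. Interferon-stimulated genes had a median of 0.41 over 35 members, 0 called by edgeR over all genes and 3 when adjusted over the list alone. Of them 13 were at an unadjusted p under 0.05, and DESeq2 called 4 (list adjusted p = 9.65e-08, and adjusted p = 0.633 with an estimated correlation), with Rsad2 at 2.02 and Oas3 at 2.07. Their per-library medians overlapped, with 0.07 in vincristine replicate 2 and 0.45 in vehicle replicate 2, and leaving out vehicle replicates 2 and 3 and vincristine replicate 2 in turn gave list medians of 0.82, 0.22 and 0.63. With sample quality weights, chosen after seeing the data, the median was 0.13 (adjusted p = 0.0151). Complement genes had a median of 0.36 over 20 members, 0 called over all genes and, adjusted over the list alone, 7 higher and 1 lower. At an unadjusted p under 0.05, 8 were higher and 1 lower, and DESeq2 called 6 higher and 1 lower (list adjusted p = 2.82e-05, and adjusted p = 0.551 with an estimated correlation); C3, C3ar1 and C5ar1 had log2 fold changes of 1.33, 0.51 and 1.34.

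Neuronal lists were lower mainly in vincristine replicate 1, and edgeR called no member of them. At an unadjusted p under 0.05 there were 4 lower potassium and HCN channels, 2 lower non-peptidergic markers, 2 lower and 1 higher peptidergic markers and 1 lower marker of myelinated neurons. DESeq2 called 0 in these lists. Potassium and HCN channels had a median of -0.42 over 45 members (adjusted p = 2.47e-07, and adjusted p = 0.633 with an estimated correlation). Against the vehicle mean the channel medians were -1.10 in vincristine replicate 1, -0.19 in replicate 2 and -0.11 in replicate 3. Without vincristine replicate 1 the list median was -0.17, and the list kept its call with the preset correlation (camera adjusted p = 0.00084). Kcnj3 (-0.67), Kcnip1 (-0.68) and Kcna2 (-0.33) did not pass. Non-peptidergic nociceptor markers had a median of -0.47 over 20 members, with medians of -1.33, -0.22 and -0.23 in the vincristine replicates (adjusted p = 0.000517, adjusted p = 0.633 with an estimated correlation, and adjusted p = 0.0967 with a median of -0.25 without replicate 1). Agtr1a and Wnt2b had log2 fold changes of -0.72 and -0.51, and Mrgprd went from 160 ± 27.0 to 79.4 ± 48.5 CPM; none passed. Peptidergic nociceptor markers had a median of -0.41 over 14 members (adjusted p = 0.0220, adjusted p = 0.725 with an estimated correlation, and adjusted p = 0.947 with a median of -0.11 without replicate 1; adjusted p = 0.0544 without vehicle replicate 2). Calca, which encodes the peptide CGRP, was at 963 ± 20.2 CPM in vehicle and 573 ± 207 CPM in vincristine (edgeR adjusted p = 0.391). Markers of myelinated and low-threshold neurons had a median of -0.23 over 24 members (adjusted p = 0.00135, adjusted p = 0.633 with an estimated correlation, and adjusted p = 0.126 with a median of -0.10 without replicate 1), and their median was -0.40, -0.40 and -0.45 without vehicle replicate 1, vincristine replicate 2 and vincristine replicate 3.

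By edgeR 0 members of the channel and receptor lists that follow were called. Sodium channels had a median of -0.32 over 13 members (adjusted p = 0.00515, adjusted p = 0.633 with an estimated correlation, and adjusted p = 0.154 with a median of -0.13 without vincristine replicate 1). Without vehicle replicate 1, vincristine replicate 2 and vincristine replicate 3 that median was -0.54, -0.52 and -0.51. At an unadjusted p under 0.05 there was 1 sodium channel, which was lower, and DESeq2 called 0. The pain-related channel genes Scn9a, at 473 ± 96.5 CPM in vehicle and 344 ± 164 CPM in vincristine, and Scn10a, at 619 ± 153 and 366 ± 216 CPM, did not pass (edgeR adjusted p = 0.689 and 0.610). TRP, Piezo, ASIC and P2X channels had a median of -0.27 over 25 members (adjusted p = 0.0137, adjusted p = 0.633 with an estimated correlation, and adjusted p = 0.258 with a median of -0.12 without vincristine replicate 1; adjusted p = 0.0510 with a median of -0.11 without vehicle replicate 2). Of these, 2 were higher and 2 lower at an unadjusted p under 0.05, and DESeq2 called 1 lower. The capsaicin receptor gene Trpv1 was at 89.1 ± 11.2 and 84.6 ± 37.1 CPM, a log2 fold change of -0.07 ± 0.33 that turned to 0.24 without vincristine replicate 1 and 0.05 without vehicle replicate 2. Trpa1 (-0.73 ± 0.40) did not pass (edgeR adjusted p = 0.549), and neither did the calcium channel subunit gene Cacna2d1 (0.60 ± 0.32, edgeR adjusted p = 0.537). Opioid and other inhibitory receptors had a median of -0.31 over 20 members (adjusted p = 0.00535, adjusted p = 0.633 with an estimated correlation, and adjusted p = 0.126 with a median of -0.12 without vincristine replicate 1); Oprd1, the delta opioid receptor gene, had a log2 fold change of -1.55 ± 0.43 and passed by DESeq2, not by edgeR (edgeR adjusted p = 0.238). Of them 1 was higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 1 lower. The median of these receptors was -0.21 without vehicle replicate 3 and -0.48 without vincristine replicate 3.

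**Figure D4:**
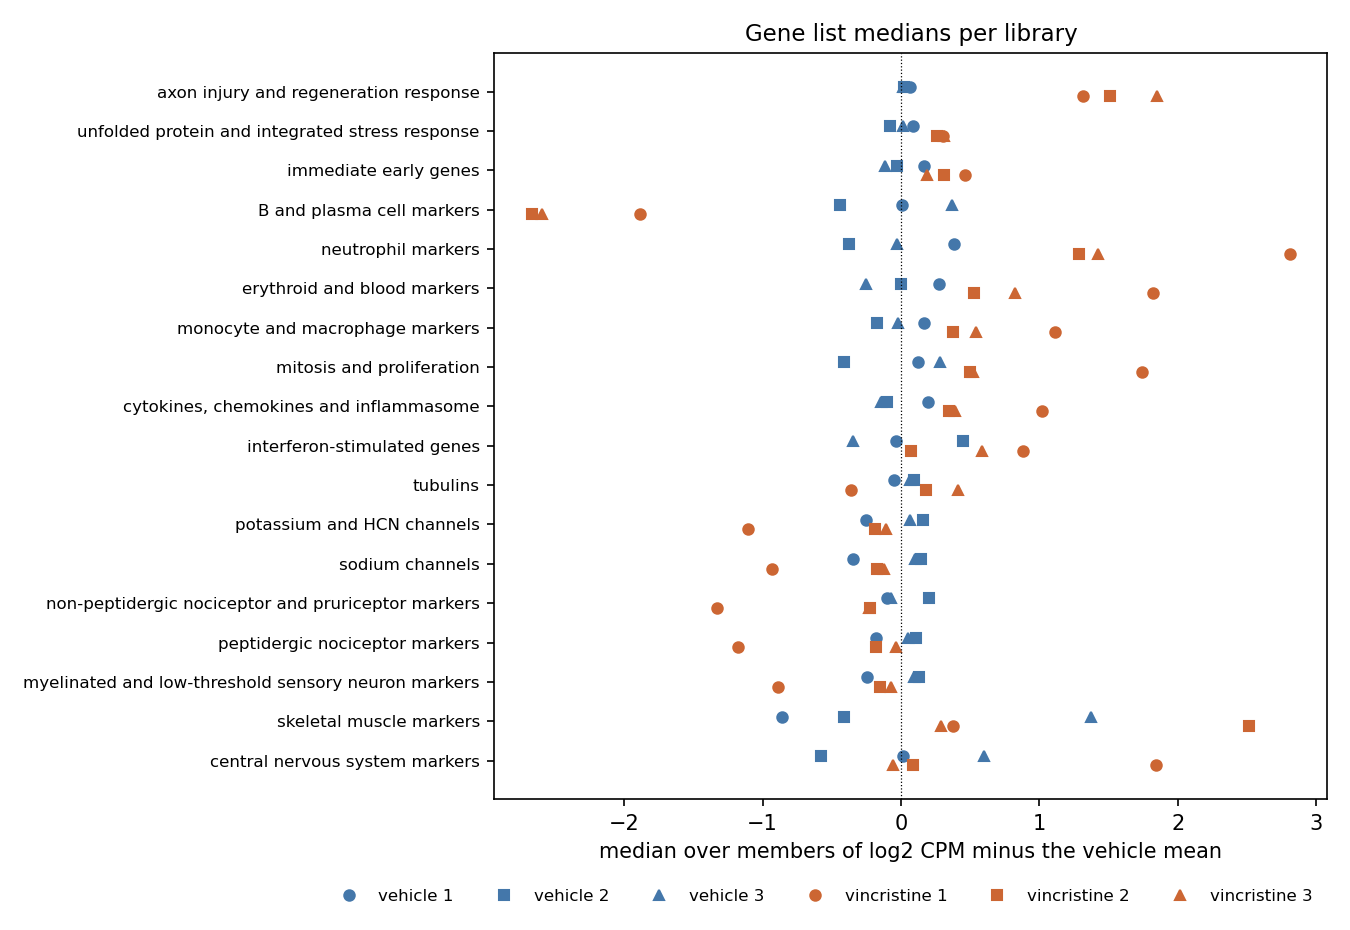
Median over list members of log2 CPM minus the mean of the vehicle libraries (horizontal axis) for 18 gene lists in each of the 6 libraries; blue marks are vehicle, orange marks are vincristine, and the marker shape gives the replicate. The injury and B-cell lists part the groups in each library. So do the neutrophil, erythroid, monocyte, cell-division, cytokine, unfolded protein and immediate early lists. The neuronal lists are lower mainly in vincristine replicate 1 (-1.10 for potassium and HCN channels), and of them the non-peptidergic list also parts the groups.

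Tubulins, the proteins that vincristine binds, had a median log2 fold change of 0.10 over 17 tested members, 0 called by edgeR over all genes and 3 when adjusted over the list alone. At an unadjusted p under 0.05 there were 4, each higher, and DESeq2 called 3 higher (camera adjusted p = 0.0295, and adjusted p = 0.633 with an estimated correlation). Without vehicle replicate 1 the adjusted p was 0.13, and without vincristine replicate 3 the median was -0.07 (adjusted p = 0.457). Without vehicle replicate 2 and vincristine replicate 1 the median was 0.16 and 0.28. The smallest p-values were those of Tuba1c, from 5.86 ± 1.47 to 17.5 ± 3.97 CPM, and Tubb6, from 16.4 ± 4.52 to 41.6 ± 4.46 CPM, called by DESeq2 and not by edgeR (edgeR adjusted p = 0.0721 and 0.0726). The neuronal isotype gene Tubb3 was at 1258 ± 163 and 1456 ± 688 CPM, and Tubb2b at 163 ± 13.3 and 221 ± 84.2 CPM; Tubb3 turned from 0.21 to -0.14 on the log2 scale without vincristine replicate 3. Nuclear-encoded oxidative phosphorylation genes had a median of -0.16 over 52 members, 0 called by edgeR or DESeq2 and 5 lower at an unadjusted p under 0.05 (list adjusted p = 2.13e-05, and adjusted p = 0.633 with an estimated correlation), with Ndufb3 at -0.37 and Cox7b at -0.28; the median was -0.10 without vincristine replicate 1. Cholesterol synthesis genes had a median of -0.21 over 24 members, 0 called by edgeR or DESeq2 and 3 lower at an unadjusted p under 0.05 (list adjusted p = 0.000130, adjusted p = 0.633 with an estimated correlation, and adjusted p = 0.0881 with a median of -0.07 without vincristine replicate 1), with Lss at -0.28 and Cyp51 at -0.29. Their median was -0.32 without vincristine replicate 3.

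Markers of neighbouring tissue differed between libraries more than between groups. Skeletal muscle markers had a median of 1.02 over 18 members, 0 called by edgeR or DESeq2 and 2 higher at an unadjusted p under 0.05 (list adjusted p = 0.00222, and adjusted p = 0.714 with an estimated correlation), with medians of 2.52 in vincristine replicate 2 and 1.37 in vehicle replicate 3; Mb and Myh2 had log2 fold changes of 1.66 and 1.26. The muscle median was -0.01 without vincristine replicate 2 (adjusted p = 0.508), 0.63 without vehicle replicate 1 (adjusted p = 0.0858), and 0.66 and 2.16 without vehicle replicates 2 and 3. Central nervous system markers had a median of 0.75 over 16 members, 0 called by edgeR or DESeq2 and 1 lower at an unadjusted p under 0.05 (list adjusted p = 0.0295, and adjusted p = 0.725 with an estimated correlation), with 1.85 in vincristine replicate 1 and 0.09 and -0.06 in replicates 2 and 3. Their call ended without vincristine replicate 1 (median -0.02, adjusted p = 0.574), vehicle replicate 1 (adjusted p = 0.0761) or vehicle replicate 2 (median 0.48, adjusted p = 0.160), and the median was 1.20 without vehicle replicate 3; Gad2 and Slc32a1 had log2 fold changes of 1.69 and 1.59. Of the 46 lists tested, 25 passed with the preset correlation, 15 higher and 10 lower. Among the 10 splits of the 6 libraries into 3 and 3, 7 gave at least as many lists, the real split included. The other splits still hold part of the treatment difference, so this count cannot decide whether list calls come from the treatment. A list call with the preset correlation does not by itself point to the treatment. With an estimated correlation 0 passed by camera, where 5 were at an unadjusted p under 0.05 and the rotation test fry called 2.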

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

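The tests in this part were set before their values were computed. Reads outside annotated genes, which enter none of the comparisons of genes, took a larger share of all tallied alignments in each vincristine library than in the highest vehicle library: 24.8% in vincristine replicate 1, 17.0% in replicate 2 and 15.6% in replicate 3, against 14.8% to 15.3% in vehicle (exact two-sided permutation p = 0.1, the smallest that 3 against 3 samples can give). As a share of uniquely aligned reads, the values were 39.7%, 24.7% and 23.5% against 22.6% to 25.8%, so that replicate 1 alone lay above the vehicle range and the excess in replicates 2 and 3 rests on the denominator. Genomic DNA as a source for the excess in replicate 1 is argued against by the olfactory and vomeronasal receptor genes, whose reads rose over the vehicle share by 0.623% of what evenly spread genomic reads would add (40.5 reads against 6502). More unspliced or nuclear RNA stays open: the 12 nuclear-retained long non-coding RNAs had a median log2 difference of 0.24 between replicate 1 and the vehicle mean, 8 of 12 were higher, and their SD was 0.56. Vincristine treatment itself is a further candidate that was not tested, and the size of the excess differed between the vincristine libraries.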

How the results depend on the processing

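Sample quality weights, the newer dispersion method of edgeR and DESeq2 with a library left out were chosen after seeing the data; the other alternatives were set before. The count of 60 called genes was 551 by DESeq2, 35 by limma-voom, 99 with no filter on low counts, 125 at an adjusted p under 0.1, 474 with sample quality weights and 600 by DESeq2 without vincristine replicate 1; each of these shared 35 to 60 genes with the 60. Leaving out 1 library gave 0 to 346 genes: 346 without vincristine replicate 1, 6 and 18 without vincristine replicates 2 and 3, and 0 by edgeR without vehicle replicate 1, 2 or 3, where 1462, 1063 and 1409 genes had an unadjusted p under 0.05 and DESeq2 called 316, 206 and 319. The cause was not tested. Each of these fits had 3 residual degrees of freedom, so that number does not set them apart. The common biological coefficient of variation was 0.125 without vincristine replicate 1 and 0.186 to 0.211 without any other library. Other scalings, a stricter filter, thinned counts, no mitochondrial genes, robust=FALSE and the newer dispersion method gave 42 to 64; the planned legacy setting is the default of the version used and moved nothing. The 25 called lists became 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 2 by fry, the injury and stress response lists. Under the other alternatives 23 to 29 lists were called: 17 of the 25 were shared without vincristine replicate 1, 22 without vehicle replicate 1, without vehicle replicate 2 or with sample quality weights, and 24 or 25 otherwise.

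The replicate numbers are not stated to mark shared animals or days. Deviations from the group means correlated at 0.43, 0.25 and -0.09 for numbers 1, 2 and 3, and vehicle replicate 2 correlated best with vincristine replicate 3 (0.49), so the numbers were not taken to pair the samples. With the replicate number as a block, 261 genes and 25 lists were called.

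No called gene changed sign under DESeq2, the RLE factors, library sizes alone, the block or with any library left out. For all 60 called genes the groups did not overlap, so a change of sign was hardly possible and its absence adds little. Among lists past the threshold, with all libraries or where the sign changed, medians that changed sign when 1 library was left out ranged from -0.067 to 0.28 for tubulins, -0.36 to 0.067 for microtubule-associated proteins, -0.042 to 0.32 for MHC class II, -0.25 to 0.19 for fibroblast and matrix genes, -0.0097 to 2.16 for skeletal muscle, -0.021 to 1.20 for central nervous system and -0.58 to 0.59 for bone markers; the cause was not tested. Other medians, not past the threshold where the sign changed, were those of the myelinating Schwann cell, endothelial, pericyte, adipocyte, ribosomal, heat shock, axon degeneration, meningeal and small RNA lists. With sample quality weights the TRP, peptidergic and central nervous system lists lost their calls (adjusted p = 0.0556, 0.128 and 0.629), the mitochondrially encoded and small RNA lists gained them (0.0248 and 0.0241), the interferon median was 0.13, and the T and NK cell median -0.039. Depth limits genes of low count.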

Other observations

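The test of scaling on the B-lineage genes was chosen after the result was seen; the other tests in this part were set before their values were computed, but the B-lineage and red cell patterns were noticed in the called genes first, and the supplementary lists of B-cell precursor, mature B-cell, immature red cell and globin genes were written after that. Beyond the genes named by rule, and named here after their values were seen, the called genes included Plaur, the urokinase receptor gene (7.18 ± 0.637 to 28.4 ± 4.67 CPM; SD, n = 3 each), Lgals3, which encodes galectin-3 (21.8 ± 4.57 to 75.8 ± 9.39 CPM), and Lamb3, a laminin chain gene (log2 2.48 ± 0.29 SE). The one-carbon enzyme gene Mthfd2 (log2 1.14 ± 0.11) and the amino acid transporter gene Slc7a5 (1.01 ± 0.13) rose too, as did Adam8 (1.72 ± 0.23), Pim1 (1.44 ± 0.18) and the kinesin gene Kif22 (1.51 ± 0.21). Genes on the opposite strand overlap Adam8, Pim1 and Kif22, and also Tmcc2 and Lgi4 named below. Nfil3 of the circadian list passed by DESeq2 and not by edgeR (log2 1.14 ± 0.18, edgeR adjusted p = 0.0698). In the mast cell list Hdc, which makes histamine, had a log2 fold change of 1.81 and the mast cell protease gene Mcpt4 of -0.39; edgeR called neither, and DESeq2 called Hdc.

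Glial, vascular and connective tissue lists stayed short of the threshold over all 6 libraries. Satellite glial markers had a median log2 fold change of 0.16 (Gfap 1.21, Lgi4 0.45), repair Schwann cell genes 0.20, myelinating Schwann cell markers 0.04, endothelial markers 0.06, pericyte and smooth muscle markers 0.18, and meningeal markers -0.08. The medians were 0.53 for T and NK cell markers, -0.39 for mast cell markers, 0.35 for adipocyte markers, -0.18 for calcium channels, -0.14 for microtubule-associated proteins and motors, -0.07 for the axon degeneration list, -0.10 for heat shock genes, -0.15 for circadian genes, 0.04 for ribosomal proteins, -0.14 for mitochondrially encoded genes, -0.15 for small structured RNAs and 0.09 for nuclear-retained RNAs. The median, the mean and the direction of the test differed in sign for MHC class II genes (median 0.16, mean -0.13), fibroblast and matrix genes (median -0.03, mean 0.02) and bone and cartilage markers (median -0.15, mean -0.13, test upward). Leaving out 1 library brought some of these lists past the threshold. Without vehicle replicate 1 these were the T and NK cell, calcium channel, microtubule-associated and myelinating Schwann cell lists; without vehicle replicate 2 the T and NK cell, mast cell and small RNA lists; and without vehicle replicate 3 the adipocyte, circadian, bone and small RNA lists. Without vincristine replicate 1 these were the meningeal, mitochondrially encoded, MHC class II, fibroblast, microtubule-associated and small RNA lists, without vincristine replicate 2 the T and NK cell list, and without vincristine replicate 3 the microtubule-associated, pericyte and fibroblast lists.

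With 3 samples against 3 there are 10 splits, so the share of splits with a result as large cannot go under 0.1. The real split gave 60 called genes and the highest of the others 0, and 1 of the 10 splits, the real one, gave as many. The other 9 splits were fitted by edgeR, with 63 to 1675 genes at an unadjusted p under 0.05. Each of them mixes vehicle and vincristine libraries in both groups. Large differences between the treatments then widen the spread within groups, so few calls were likely from the start. Part of the treatment difference also stays between the mixed groups, which bears on the list counts. For the lists with the preset correlation the real split gave 25 and the highest of the others 32, with 7 of 10 splits as large. The number of lists called thus does not set the real split apart.

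The fall of B-lineage genes may reflect fewer B cells or B-cell precursors in or near the ganglia. Less bone marrow or blood of unchanged make-up carried along with the ganglia would lower neutrophil genes too. The neutrophil median lay 4.54 above the B-lineage median on the log2 scale (SD of members 0.32 for neutrophil and 2.17 for B-lineage genes). Whether the make-up of blood or marrow changed was not tested, so this gap cannot exclude less carry-over together with such a change. In vincristine replicates 1, 2 and 3 the neutrophil medians were 2.81, 1.28 and 1.42 and the B-lineage medians -1.89, -2.66 and -2.59 against the vehicle mean. Members of a list vary together (estimated correlation 0.93 and 0.61), so they are not independent replicates of this difference. A scaling factor moves every gene of a library alike. The B-lineage median lay at -2.55 relative to the median of all genes tested, more than the SD of its members (2.17). That value nearly restates the fall that prompted the test, so it is no separate support. Another scaling moved the median gene by at most 0.0159 on the log2 scale, so the choice among scalings was too small to account for the fall. The median was -1.15 over 6 B-cell precursor genes, 2 of them called, and -1.97 over 8 mature B-cell genes, 1 of them called. A loss of B cells from blood or marrow as a drug effect, and a change in which tissue was dissected, stay open and were not tested.

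Erythroid genes were higher in vincristine, most in replicate 1, and more whole blood left in the tissue is a candidate explanation. The mean log2 ratio of immature red cell genes to globins was 0.29 above the vehicle mean in vincristine replicate 1, inside the vehicle range (-4.20 against -4.80 to -4.07). In vincristine replicates 2 and 3 the ratio was -3.70 and -3.69, above that range, and 5 of the 6 immature red cell genes (Trim58, Slfn14, Tmcc2, Ranbp10 and Ypel4) were picked because they were called higher, which raises the ratio by itself. The ratio therefore decides nothing, and more blood in the tissue stays open. The median log2 fold change was 1.58 over these 6 genes and 1.08 over 4 globins, with Hbb-bs at 2129 CPM in vehicle and 4563 CPM in vincristine. A change in the make-up of blood or marrow after the drug stays open too.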
